A study of Mus musculus and Rattus norvegicus with 4 samples.

How the data were processed

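Genomic DNA of 2 allodiploid embryonic stem (ES) cell lines, RM1-1 and MR1-1, was measured by array comparative genomic hybridisation (array CGH), a method in which 2 DNA samples carrying different dyes compete for the same probes and the ratio of the dyes gives the relative copy number at each probe. Each line was hybridised to 1 array of mouse probes against normal mouse ES cells and to 1 array of rat probes against normal rat ES cells, which makes 4 arrays. The DNA of a hybrid line also holds the genome of the other species, whose conserved exons could bind the probes. The size of this binding was not estimated, so a ratio need not reflect the copy number of 1 species alone. Per the labels' protocols, the cells were grown in N2B27 medium with 2i and LIF, sorted in G0/G1, and equal numbers of cells were used for the DNA of both channels. The scanner images were processed with Agilent Feature Extraction 10.7, per the submitters' processing notes.

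The deposited values are log2 ratios of the 2 channels, 1 per probe, 46227 on the mouse design and 49208 on the rat design, with 0 missing values and 0 repeated probe IDs. The log base, the dye normalization and which channel is the numerator are not given in the sources used here, so log2 is a reading of the values. A base of 10 would make the lowest rat value, -5.94, an 865167-fold ratio, beyond the range of a 16-bit scanner, whose log10 is 4.82. A natural log was not excluded and would make each value 1.44 times as large on the log2 scale. The labels' labelling protocol puts the test DNA in Cy5 and the control DNA in Cy3, while the channel labels put the hybrid line in Cy3 and the normal cells in Cy5. The direction of the ratio therefore stays open, and "above" and "below" refer to the deposited sign. The deposited medians were -0.20 for RM1-1 and -0.20 for MR1-1 on the mouse array and -0.30 and -0.28 on the rat array, so the values were not centred on the median of all probes. They were centred here by subtracting each array's median, with no loess or quantile step. The number of arrays, 1 for each line and species, limits the precision: without replicates, no significance test of a difference in ratio between lines or against normal cells was made. Shuffles of the probe order and random placements of runs, used for the order and position of probes, describe these arrays only. Intervals (95%) come from 1000 resamplings of blocks of 10 neighbouring probes, or of single probes in runs under 100 probes, and cover probe noise on these arrays only.

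The probe IDs were not paired with genes, sequences or genome coordinates in the files used here, and the mouse gene table at hand (assembly GRCm38.p6) lists no probe IDs. The planned medians by chromosome, the fixed gene lists (pluripotency, cell cycle and tumour, imprinted, X-linked, Y-linked, copy number variable families, and diploid controls), the contrast of exonic with other probes, the comparison of the same gene on the mouse and rat arrays, and the corrections for GC content were therefore not run, and no gene or chromosome is named in the results. Under the rule fixed before the data were examined, the 2 highest and 2 lowest probe IDs of each array stand in their place. The planned change-point analysis needed an order of the probes. The order of the probe IDs was used instead, a choice made after seeing the data, and positions below are places in that order, counted from 1.

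Change points were found by penalised least squares with a penalty of 5 times the noise variance times the natural log of the number of probes, at least 10 probes per segment, after pulling in probes farther than 3 robust SD from the running median of 11 neighbours. A segment was called where its median lay at least 0.3 from the array's centre. The same method was applied to the difference of the 2 lines on one design. Tested on simulated data (200 segments planted into the real values after removal of their running median and shuffling), the method made 0 calls outside planted segments. The shuffling removed any correlation of neighbouring probes, so the simulation covers noise without order only. In the real order the next-probe correlation was 0.56 to 0.65 on single arrays, and 0.097 (mouse) and 0.012 (rat) in the line differences. In the line difference on the mouse design it recovered all 23 of the 10-probe segments shifted by 0.75 and 34.8% of those shifted by 0.5; on the rat design it recovered all 23 and 39.1%. On single arrays the shares at 10 probes and 0.75 were 4.35% for RM1-1 and 21.7% for MR1-1 on the mouse design, 13.0% and 39.1% on the rat design. Larger blocks were defined from the mean of both lines with a penalty of 40 (12 inside intermediate blocks). A block was called raised or low where its median lay at least 0.5 above or below that of the block with the most probes, intermediate from 0.1 to 0.5, and baseline otherwise. Stretches of IDs that end with a raised block, and with a low block where one follows, are called ID series: 3 on the mouse array, after a family of 330 probes with another ID prefix, and 2 on the rat array. Alternatives were other centrings, a log10 reading, penalties of 3 and 10, minimums of 5 and 20 probes, call thresholds of 0.2 and 0.5, means in place of medians, and leaving out extreme probes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.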

Results

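Allodiploid ES cells carry a chromosome set from each of 2 species in one nucleus, here mouse and rat. The arrays asked how the mouse and the rat share of the genome of 2 such lines compared in copy number with normal ES cells of each species, and whether the lines differed from each other. Each line was measured on 1 mouse array of 46227 probes and 1 rat array of 49208 probes, so all values stand without replicates and errors describe the spread over probes. Neighbouring probes differed with a noise SD of 0.23 on both mouse arrays, of 0.24 for RM1-1 on the rat array and of 0.22 for MR1-1 on the rat array, on the log2 scale. After centring on the median, probes beyond 1 from the centre lay mostly above it in the deposited orientation, whose direction is not settled: 1333 above and 212 below for RM1-1 and 1799 above and 206 below for MR1-1 on the mouse array, and 2295 above and 220 below for RM1-1 and 2399 above and 178 below for MR1-1 on the rat array. Beyond 0.5, the mouse array had 6968 probes above and 2376 below for RM1-1 and 7416 above and 2281 below for MR1-1, and the rat array 7979 above and 2491 below for RM1-1 and 7741 above and 1887 below for MR1-1. This split depended on the centre. In the values as deposited, 4310 probes lay above 0.5 and 7055 below -0.5 for RM1-1 and 5051 and 7078 for MR1-1 on the mouse array, and 4402 and 12100 for RM1-1 and 4633 and 10384 for MR1-1 on the rat array. Beyond 1 the uncentred split was 386 above and 451 below for RM1-1 and 562 and 408 for MR1-1 with mouse probes, and 552 and 790 for RM1-1 and 669 and 536 for MR1-1 with rat probes. The steps between blocks of one array do not depend on the centre.

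In both lines most of the mouse and rat probes lay at a common level, and a minority lay higher in the deposited orientation by 0.75 to 0.88 on the log2 scale. Ordered by probe ID, the high probes formed 3 long raised blocks on the mouse array (664, 2743 and 4709 probes) and 2 on the rat array (5195 and 2362 probes), with the same boundaries in both lines because blocks were defined on their mean. Over the baseline of the same array the mouse blocks were raised by 0.78 in RM1-1 (95% interval 0.77 to 0.80, 8116 probes) and by 0.85 in MR1-1 (0.84 to 0.87), which are 1.72-fold and 1.81-fold on a linear scale if the deposited values are log2. The rat blocks were raised by 0.88 in RM1-1 (0.86 to 0.89, 7557 probes) and by 0.88 in MR1-1 (0.87 to 0.90), or 1.84-fold in both lines. Each ID series gave the step on its own. On the mouse array it was 0.79, 0.75 and 0.78 in RM1-1 and 0.87, 0.82 and 0.85 in MR1-1; on the rat array it was 0.88 and 0.87 in RM1-1 and 0.88 and 0.88 in MR1-1. The blocks were chosen by their level in the same probes, so the intervals leave out the effect of that choice.

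**Figure D1:**
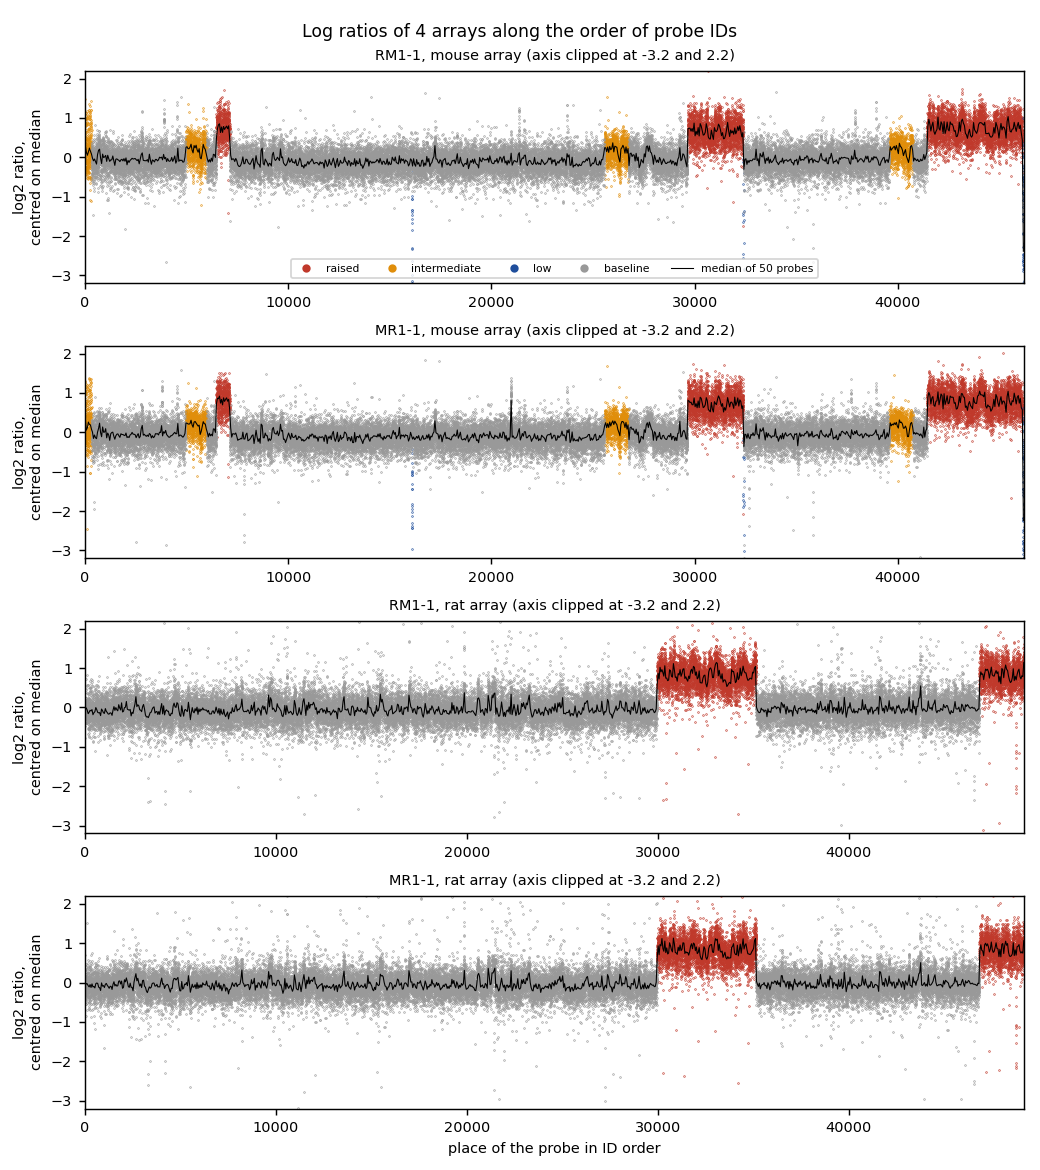
Centred log2 ratio of every probe (y axis, clipped as its title states) against its place in the order of probe IDs (x axis) for each line and array; colours mark baseline, intermediate, raised and low blocks and the black line is the median of 50 neighbouring probes. The raised blocks lie 0.75 to 0.88 above the baseline of their series, and the low blocks appear on the mouse array. All blocks were defined on the mean of both lines, so their places are the same in both by definition.

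The next-probe correlation along the ID order was 0.62 for RM1-1 and 0.65 for MR1-1 on the mouse array and 0.56 and 0.57 on the rat array, against a largest absolute value of 0.0142, 0.0106, 0.0138 and 0.0111 in 100 shuffles of each. The ID order gives no genome coordinates.

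Segments called below the centre were short, with 137 probes in RM1-1 and 216 in MR1-1 on the mouse array and 10 in each line on the rat array. Directly after the second and the third raised block of the mouse array followed low blocks of 20 and 89 probes. The first had a centred median of -1.62 in RM1-1 (SD 1.38 over probes) and -1.80 in MR1-1 (SD 1.39), the second of -1.56 (SD 1.36) and -1.59 (SD 1.33). A further low block of 21 probes lay inside the second ID series and had a median of -1.84 in RM1-1 (SD 0.96) and -1.45 in MR1-1 (SD 0.70). No block of the rat array was low, but a run of 10 probes inside its second raised block was called below in both lines, at -1.22 in RM1-1 and -1.24 in MR1-1. The probes with the lowest values were A_67_P22308447 and A_67_P22306634 for RM1-1 and A_67_P22308447 and A_67_P09496752 for MR1-1 on the mouse array, with centred ratios of -4.65 and -4.64, and of -4.91 and -4.71. All 3 probes lay in the low blocks after raised blocks. Among rat probes the lowest were A_86_P03259768 at -5.61 and A_86_P16578641 at -5.30 in RM1-1, and A_86_P16578641 at -5.65 and A_86_P02410847 at -4.74 in MR1-1.

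The highest mouse probe was the same in both lines. The highest rat probe was not, but that of each line also lay far above the centre in the other. A_67_P21855307 was highest on the mouse array, at 3.15 in RM1-1 and 2.96 in MR1-1, followed by A_67_P22305164 at 3.11 in RM1-1 and A_67_P21862706 at 2.76 in MR1-1. With rat probes, A_86_P17936208 at 5.42 and A_86_P21588416 at 5.14 were highest in RM1-1, and A_86_P05371805 at 5.82 and A_86_P21588416 at 5.66 in MR1-1. In the other line, A_86_P17936208 stood at 5.60 (MR1-1) and A_86_P05371805 at 4.63 (RM1-1).

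Segmentation of each array called 23 segments above and 6 below the centre for RM1-1 and 21 above and 9 below for MR1-1 on the mouse array. On the rat array it called 34 above and 1 below for RM1-1 and 32 above and 1 below for MR1-1. Of the segments above the centre, 14 with 8116 probes in RM1-1 and 12 with 8114 probes in MR1-1 subdivided the mouse raised blocks, and 20 with 7547 probes and 19 with 7549 probes subdivided those of the rat. Segments above the centre outside the raised blocks held 212 probes in RM1-1 and 238 in MR1-1 on the mouse array, and 543 and 473 on the rat array. This share depended on the threshold. At 0.2, all segments above held 11479 probes in RM1-1 and 9850 in MR1-1 on the mouse array, against 8328 and 8352 at 0.3. On the rat array they held 9023 and 9257, against 8090 and 8022. Within the mouse raised blocks segment medians ran from 0.52 to 0.86 in RM1-1 and from 0.56 to 0.98 in MR1-1, and the longest segment held 1451 probes in both. The number of segments above the centre followed the penalty: for RM1-1 on the mouse array it was 46 with a penalty of 3 and 10 with a penalty of 10.

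The 2 lines differed from each other at 9 short runs of the mouse array and at 0 runs of the rat array. In 3 runs MR1-1 was higher, with 17, 43 and 11 probes, 1 in each ID series, and it had centred medians of 0.78 (SD 0.26 over probes), 0.91 (SD 0.27) and 0.86 (SD 0.22), and RM1-1 0.21 (SD 0.22), 0.14 (SD 0.27) and 0.11 (SD 0.25). In another 3 runs RM1-1 was higher, with 15, 12 and 14 probes, again 1 in each series. RM1-1 had 0.95 (SD 0.20), 1.01 (SD 0.26) and 0.88 (SD 0.26), and MR1-1 0.21 (SD 0.20), 0.17 (SD 0.16) and 0.04 (SD 0.19). In 2 runs of 11 and 10 probes, in series 2 and 3, MR1-1 was low, at -1.12 (SD 0.96) and -1.19 (SD 0.82), while RM1-1 stood at -0.08 (SD 0.20) and -0.10 (SD 0.17). The last run was the low block of 21 probes, lower in RM1-1 than in MR1-1.

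The difference of RM1-1 minus MR1-1 in the runs higher in MR1-1 was -0.82 (95% interval -0.88 to -0.71), -0.75 (-0.80 to -0.71) and -0.75 (-1.08 to -0.70), with all 17, 43 and 11 probes in that direction. In the runs higher in RM1-1 it was 0.79 (0.65 to 0.98), 0.77 (0.57 to 0.89) and 0.89 (0.59 to 1.00), with all 15, 12 and 14 probes in that direction. In the runs low in MR1-1 it was 0.90 (0.22 to 1.64, 10 of 11 probes) and 1.03 (0.22 to 1.56, 9 of 10 probes), and in the 21-probe low block -0.37 (-0.52 to -0.33, 20 of 21 probes). The 9 differences were larger in size than those of 99.81% (the 21-probe block) or more of 10000 random windows of as many probes on the same arrays. The runs were found and measured in the same probes, which pushes their differences away from 0. The windows were drawn from the same differences, runs included, so a rank near the top follows from how the runs were chosen and lends them no support. With a minimum of 20 probes both runs low in MR1-1 were lost, with a penalty of 10 the 11-probe run low in MR1-1 and the 21-probe block, and with a threshold of 0.5 the 21-probe block.

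**Figure D2:**
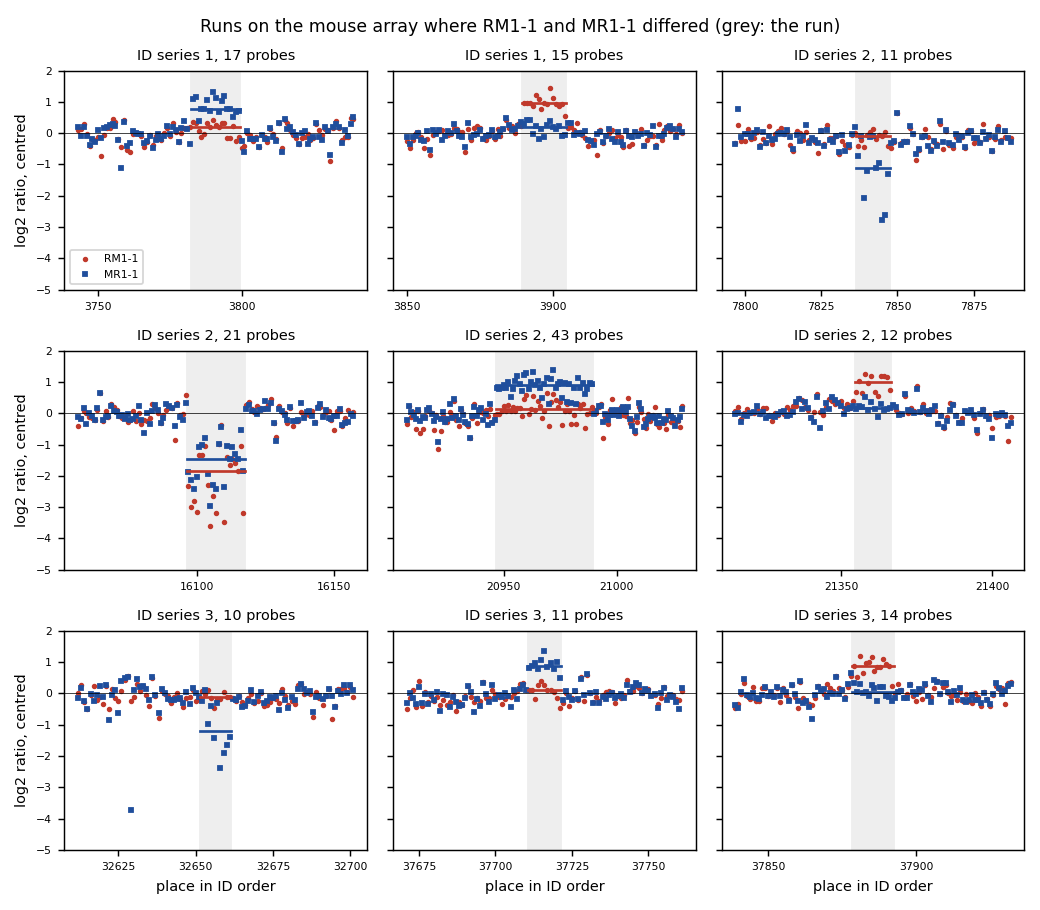
Centred log2 ratio (y axis) of single probes of RM1-1 (red circles) and MR1-1 (blue squares) against place in ID order (x axis) around the 9 runs of the mouse array in which the lines differed; grey marks the run and horizontal lines the medians in it. MR1-1 is higher in 3 runs (17, 43 and 11 probes), RM1-1 in 3 (15, 12 and 14 probes), and MR1-1 is low in 2 (11 and 10 probes).

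At the level of whole raised blocks the lines differed little. The mouse raised blocks stood higher over the baseline in MR1-1: the step of the difference of RM1-1 minus MR1-1 was -0.067 over all 3 blocks (95% interval -0.071 to -0.061), and -0.061, -0.067 and -0.068 in the single ID series. For the rat blocks it was -0.0072 (-0.013 to -0.003). In simulated rat differences all 22 planted segments of 20 probes shifted by 0.5 were recovered, against 39.1% of those of 10 probes, so short or small differences between the lines could be missed.

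Across probes, which are not independent replicates, RM1-1 and MR1-1 correlated with a Pearson r of 0.91 (Spearman rho 0.88, covariance 0.17) on the mouse array and of 0.91 (rho 0.87, covariance 0.19) on the rat array. Over baseline probes alone, a choice made after seeing the data, r was 0.78 on the mouse array (34244 probes) and 0.84 on the rat array (41651 probes). Both lines were set against normal cells of the same kind with the same probes, and a part of the correlation may come from that shared reference. Its size was not estimated, since the intensities of the single channels were not analysed here.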

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

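Of 236 alternative values for 61 results, 176 stayed within the bounds set for the main value and 60 moved. The bounds for counts were wide. A rise from 8328 to 11479 probes in segments above the centre (RM1-1, mouse array, threshold of 0.2) counted as unmoved. The 176 include the rat line-difference counts, 0 under every setting, and the 60 include the log10 reading, so the totals say little about stability. A change of sign could be recorded only for the 18 values of runs and the 12 of steps, of which 0 reversed. Some values could not move: the 4 robust SDs do not depend on the centring, and leaving it out shifts all runs by the same constant. The ordering by probe ID, the baseline-only and 50-probe correlations, and the alternatives for steps and runs were chosen after seeing the data. All 18 alternative values of the 9 runs (means, no centring) stayed within the SD over the run's probes. This outcome was fixed, since a mean lies within 1 SD of its median and the constant from centring was small. All 12 of the raised-block steps (means, without the 5% farthest probes) stayed within the SD over all baseline probes, a wide bound. Neither outcome lends support to the runs or the steps. A minimum of 20 probes gave 3 mouse segments higher in RM1-1 in place of 5 and a penalty of 3 gave 8, with 100 probes in place of 62. All 9 runs were found again with a penalty of 3, 7 with a penalty of 10, 7 with a minimum of 20 probes and 8 with a threshold of 0.5. The rat line difference had 0 called runs under every setting of penalty, minimum and threshold tried. Segments above the centre numbered 46 and 39 (mouse) and 62 and 61 (rat) for RM1-1 and MR1-1 with a penalty of 3, and 10 and 9 (mouse) and 12 and 13 (rat) with a penalty of 10; the mouse segments of MR1-1 below the centre fell from 9 to 5 and their probes from 216 to 132 with a penalty of 10, and the 1 rat segment below, of 10 probes, gave 0 segments and 0 probes at a minimum of 20 because it is shorter. Counts of single probes depended on the centre and the log base. Without centring, probes above 0.5 numbered 4310 for RM1-1 on the mouse array and 4402 and 4633 for RM1-1 and MR1-1 on the rat array, those below -0.5 7055 and 7078 (mouse) and 12100 and 10384 (rat), those above 1 386 and 562 (mouse) and 552 and 669 (rat), and those below -1 451 and 408 (mouse) and 790 and 536 (rat). Centring on the mode moved 3 counts below 0.5, to 1533 (RM1-1, mouse), 1584 (RM1-1, rat) and 1081 (MR1-1, rat). Reading the values as log10 gave robust SDs of 1.12, 1.11, 1.11 and 1.02 in place of 0.34, 0.33, 0.33 and 0.31 (mouse RM1-1 and MR1-1, rat RM1-1 and MR1-1). In the same order, counts became 15586, 15712, 16547 and 15932 above 0.5, 14288, 14105, 15157 and 14201 below 0.5, 10837, 10843, 11489 and 10924 above 1, and 7200, 6946, 7521 and 6488 below 1. The correlation of the lines was 0.90 on the mouse array without the 1% largest ratios, 0.78 (mouse) and 0.84 (rat) over baseline probes and 0.99 in medians of 50 neighbouring probes on both designs; the cause was not tested. Autosomal centring, medians of 1 Mb bins, averaging by locus or gene and GC correction were not run, because the files used here do not pair probes with positions or genes and repeat no ID. Signal over background was not analysed here, and calls on single arrays at 10 probes and a shift of 0.75 recovered 4.35% to 39.1% of planted segments.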

Other observations

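All tests of explanations in this part were chosen after the results were seen. Both lines shared a set of further features. Outside the raised blocks, 6 runs of the mouse array, with 11 to 38 probes in RM1-1, and 12 of the rat array, with 10 to 64, were called above the centre in both lines. The highest of them on the mouse array, in ID series 3, stood at 0.97 in RM1-1 (11 probes) and 0.95 in MR1-1 (10 probes). On the rat array a run stood at 1.54 in RM1-1 (11 probes) and at 1.73 in MR1-1 (13 probes), and another of 10 probes at 1.35 and 1.36. Probes beyond 2 below the centre were shared by both lines in 59 of the 69 cases of each line on the mouse array, where independent lists would share 0.10, and 50 of the 59 lay in the low blocks, which hold 130 probes. On the rat array 74 probes beyond 2 above the centre were shared, of 83 in RM1-1 and 104 in MR1-1 (0.18 if independent). Of these 74, 67 lay in the baseline, which holds 41651 of all 49208 rat probes, so their place is close to that of probes in general. The 330 mouse probes with another ID prefix had a median of 0.16 in RM1-1 and 0.20 in MR1-1, with 24.5% and 26.1% of them above 0.5. The overlaps of independent lists leave out what both lines have in common: the reference, the probe effects and any binding of the other species' DNA. The part of the shared features that comes from these was not estimated.

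Raised blocks. From the last 50 probes before a raised block to its first 50 probes the ratio rose by 0.68 (95% interval 0.56 to 0.77) to 1.01 over the 5 block starts and both lines, or 76.4% to 128.3% of the whole step, which argues against gradual drift along the IDs. The starts were placed where these same probes jump most, which pushes the local steps upward. Their intervals leave out the effect of that choice. The lowest lower bound of a whole step, 0.73, lies above 0.585, the log2 of 1.5, which argues against a 3 to 2 ratio of copies provided that these arrays compress ratios rather than stretch them. A candidate explanation is that the raised blocks hold X-linked probes and the low blocks after them Y-linked probes, with a hybrid line that has 1 copy of each chromosome of a species, no Y of that species, and normal cells with 1 X and 2 of each autosome. The mean step of 0.85, if log2, lies below the 1 this predicts. Low blocks followed only the second and the third mouse raised block, not the first and not those of the rat array. A further low block of 21 probes lay inside the second mouse ID series, away from its raised block. The explanation cannot be told apart from others here because no annotation of the probes was used. If it held, the deposited ratio would be hybrid line over normal cells, which would settle the direction of the calls.

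Runs that differ between the lines. Shuffling the probe order 20 times gave at most 0 called runs in the mouse line difference, against 9 in the real order. Shuffles remove any correlation of neighbouring probes, so they speak only to noise without order. Expressed as a fraction of the ID range before the raised block, the runs higher in MR1-1 lay at 0.61, 0.62 and 0.62 of ID series 1 to 3, those higher in RM1-1 at 0.63, 0.65 and 0.64, and those low in MR1-1 at 0.05 and 0.06 of series 2 and 3. Of the 9 runs, 8 thus had a partner of the same direction in another series within 0.02. As many occurred in 4 of 10000 random placements (0.04%). The window of 0.02 and the scaling were chosen after the positions were seen. The share may therefore overstate how rare such matches are, and it does not exclude chance placement. Where the probes sit on the slide was not used, so the placements cannot speak to a local flaw of an array. No low run was found at the matching place of the first series. Its largest 5-probe difference in the matching range was 0.26, equalled or exceeded by 40 of its 6134 windows. That range held 584 probes, against 1855 and 700 in series 2 and 3, so a run of few probes could have been missed. Differences between the normal mouse ES cell DNA on the 2 arrays stay open for runs of up to 1.03, because the intensities of the single channels were not analysed here.

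Intermediate blocks. In each mouse ID series a stretch of 1036, 1192 or 1179 probes before the raised block (in series 3 neighbouring blocks of 41 and 1138 probes, joined here) stood above the baseline by 0.25, 0.31 and 0.24 in RM1-1 and by 0.26, 0.29 and 0.23 in MR1-1. Denser spacing of the IDs is not enough: the blocks lay at least 0.21 above baseline stretches spaced as densely. In all 3 blocks the lowest stretch of 70 probes fell to between -0.18 and -0.07, at or below the baseline. Its drop below the block's median, 0.28 to 0.36 over both lines, exceeded the 95th percentile of baseline stretches of as many probes (0.14 to 0.25). In series 2 the largest baseline drop of MR1-1, 0.31, was deeper than that of the block, 0.29. A dip of 70 probes, the width used here, had already been segmented in the first block in both lines. The levels inside the blocks were uneven, but a test of that width cannot decide on a uniform change in copy number over each block. The spread of 50-probe medians alone was less clear, above the 95th percentile of baseline stretches in 1 of the 3 blocks. A change in copy number over parts of a block, a property of the probes such as GC content, binding of the other species' DNA and a difference in the normal cells were not tested.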
